A study of Mus musculus with 16 samples.

How the data were processed

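The samples were 16 libraries of polyadenylated RNA from sections of the brachiocephalic artery, a branch of the aortic arch in which mice on a cholesterol-rich diet form atherosclerotic plaques. All mice were female and lacked Apoe, the apolipoprotein whose loss raises plasma cholesterol, and 8 of them also lacked Mif, which encodes macrophage migration inhibitory factor, a cytokine with chemokine-like activity. Per the labels' protocols, the mice ate a Western-type diet with 0.2% cholesterol and 21.2% fat from 6 weeks of age for 24 or 42 weeks. Frozen sections of 5 µm were scraped from slides with the whole vessel on them, lysates were pooled per mouse, and 1 ng of RNA was amplified by a Smart-seq2 protocol, which counts reads and has no molecular identifiers and no strand information. The libraries were made with an in-house Tn5 transposase and sequenced as read pairs of 100 bp on a DNB-seq instrument.

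The deposited count table held whole-number counts per gene symbol. Per the submitters' processing notes, the authors trimmed the reads with cutadapt 1.18 and Trim Galore 0.6.4, examined them with FastQC 0.11.5 and aligned them with STAR 2.5.2b to the mouse build GRCm39. The program that counted the reads and the gene annotation were not given in the sources used here, so no coordinates are printed. The deposited table had 55359 rows. 1 row with a blank name was left out, and its largest share was 0.00257% of the counts of 1 library (exact Clopper-Pearson 95% interval 0.00208% to 0.00315%). 2 reporter rows, GFP and TDTOM, were left out of the tests. A second deposited table held variance-stabilised values on a log2 scale made by the authors from 9578 genes, which were exactly those with at least 20 counts in at least 4 libraries. It was used as an alternative input.

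Groups were taken from the genotype and diet labels, with 4 mice per group and a separate mouse named for each library. The column names read as positions on a plate: the 4 libraries of Apoe-/-Mif-/- mice at 24 weeks lay in row C and the other 12 in row B. Row and group therefore could not be told apart for those 4 libraries. The genotype comparison at 42 weeks and the duration comparison in Apoe-/- mice lay wholly within row B, and all other comparisons crossed the rows. Within row B each group filled adjacent positions, so position along the row could not be told apart from group there either.

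The tests, the 37 gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling, the filterByExpr filter at its defaults (minimum count of 10, total of 15) and 1 fit over all 16 libraries with 12 residual degrees of freedom. The filter kept 10634 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were the effect of Mif deletion at each duration, the effect of 42 against 24 weeks in each genotype, the genotype effect averaged over both durations, and the interaction, which asks whether the genotype effect differed between durations. The first 4 share libraries in pairs, and the last 2 reuse all of them. CPM values are counts scaled by library total and TMM factor, computed here from the deposited counts.

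Gene lists for cell types, pathways and handling were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 5 tested genes. The same lists were tested with an estimated correlation and with fry. The preset value understated the correlations estimated within most of the lists reported here, and no list passed in any comparison with an estimated correlation or with the directional test of fry. The mixed test of fry, which asks for no common direction, passed 1 list for Mif deletion at 24 weeks and 6 for the interaction. A list score was the mean log2 CPM of the tested members. Mif, Apoe, Ddt and list scores were also compared by two-sided exact permutation tests of 4 against 4 libraries, for which the smallest possible p is 0.0286.

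Genes were named by rule: Mif and Apoe, up to 10 genes with the largest rise and 10 with the largest fall among those called, the called members of each list, and, where a list passed without any called member, the 2 members with the smallest p in its direction. Predicted genes and pseudogenes were left out of the ranking by size. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passed. Where such a gene had counts in fewer than 2 libraries of a group, its counts per library were given for the groups compared where it was first named.

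The scripts were tested on simulated data with the real genes, means and library sizes, with each gene drawn independently of the others. For Mif deletion at 24 weeks, 0% of genes changed 4-fold, 15.3% of those changed 16-fold, 50% of those changed 64-fold and 78% of those changed 256-fold were recovered, with 8 of 223 calls false (3.59%) over 3 simulations of 10634 genes. For the interaction the shares were 0%, 6%, 37.3% and 56.7%, with 13 of 163 calls false (7.98%). In the list test for Mif deletion at 24 weeks, 1 list of 18 genes shifted 4-fold was found with both correlations and 0 of the other lists were called. As the simulated genes were independent, these simulations could not show false gene or list calls that come from correlated genes. Regrouped real libraries gave up to 13 gene calls for Mif deletion at 24 weeks and up to 72 for the interaction. With the real 24-week libraries regrouped across genotypes, camera at the preset correlation passed a median of 7 lists (highest 19).

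Depth ran from 378066 to 8649525 counts per library. Over a group at 0 counts, 3 counts were taken as the floor, and intervals and floors cover counting error only, since amplified reads are not independent molecules. The biological coefficient of variation was 1.27, so that a gene typically varied between mice of a group by more than its own mean. The settings fixed then changed the scaling to size factors, the count filter, the libraries in the fit, the threshold, the robust setting of edgeR, the tool (DESeq2 1.42.0, limma voom with library weights, limma on the deposited values) and a covariate, the white adipocyte score, and left out each library in turn. 3 further alternatives were chosen after seeing the data: leaving out a pair of doubted libraries, thinning all libraries to the shallowest, and setting counts under 1% of a gene's highest count in the same plate row to 0. 1 share was tried for the last. The white adipocyte score comes from the same libraries and from genes tested here, among them Thrsp, Plin1, Car3, Dgat2 and Pck1. A fit with it as a covariate therefore takes away part of their own difference by construction. Python 3.11.15 with matplotlib 3.10.9 drew the figures.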

Results

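Transcripts of brachiocephalic artery sections were counted in 16 female mice. There were 4 mice in each of 4 groups, defined by genotype (Apoe-/- or Apoe-/-Mif-/-) and by time on the Western-type diet (24 or 42 weeks). The series title names aging and protection from atherosclerosis by Mif deficiency as its subject. Total counts averaged 4613000 ± 2956000 (SD, n = 4) in Apoe-/- and 3106000 ± 1571000 in Apoe-/-Mif-/- libraries at 24 weeks. At 42 weeks they averaged 2617000 ± 1864000 and 2700000 ± 1195000. The shallowest library, library 1 of the Apoe-/- mice at 42 weeks, had 378066 counts, and the deepest, library 3 of the Apoe-/- mice at 24 weeks, had 8649525. Spp1, which encodes osteopontin, took the largest share of counts in 7 libraries. Mice of the same group were hardly more alike than mice of different groups, with median Spearman correlations across genes of 0.531 over 24 pairs within groups and 0.529 over 96 pairs between groups. The share of mitochondrial transcripts ran from 0.751% to 10.2%. Group means were 4.59% ± 4.53 and 1.63% ± 0.958 at 24 weeks and 2.46% ± 0.961 and 5.97% ± 2.90 at 42 weeks (Apoe-/- first, SD, n = 4).

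The deleted gene was examined first. Mif was present at 141 ± 33.5 CPM (SD, n = 4) in Apoe-/- and 12.8 ± 6.69 CPM in Apoe-/-Mif-/- arteries at 24 weeks. The mean was 11-fold lower (exact permutation p = 0.0286, the smallest that 4 against 4 can give). At 42 weeks it was present at 160 ± 116 and 9.35 ± 5.06 CPM, a 17.1-fold lower mean (exact permutation p = 0.0286). All 8 libraries without Mif lay below all 8 with it, with at most 19.9 CPM against at least 23.2 CPM. In the edgeR test over all genes the Mif difference had log2 fold changes of -3.46 ± 1.179 (SE) and -4.11 ± 1.22. Neither passed (adjusted p = 0.341 and 0.176). The 4 Apoe-/-Mif-/- libraries at 24 weeks still held 168 Mif counts in all and those at 42 weeks 68. Reads of Mif pseudogenes can be hard to tell from those of Mif. 9 of these pseudogenes held 247, 58, 8 and 2 counts in the Apoe-/- and Apoe-/-Mif-/- groups at 24 weeks and the same groups at 42 weeks. Apoe transcripts, from the gene mutated in all 16 mice, were present at 52.7 ± 37.7 CPM with Mif and 40.7 ± 49.3 CPM without it at 24 weeks (exact permutation p = 0.771). At 42 weeks they were present at 328 ± 536 and 58.2 ± 91.4 CPM, a 5.63-fold lower mean without Mif that did not pass (exact permutation p = 0.514), and reached 1127 CPM in library 4 of the Apoe-/- mice at 42 weeks.

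**Figure D1:**
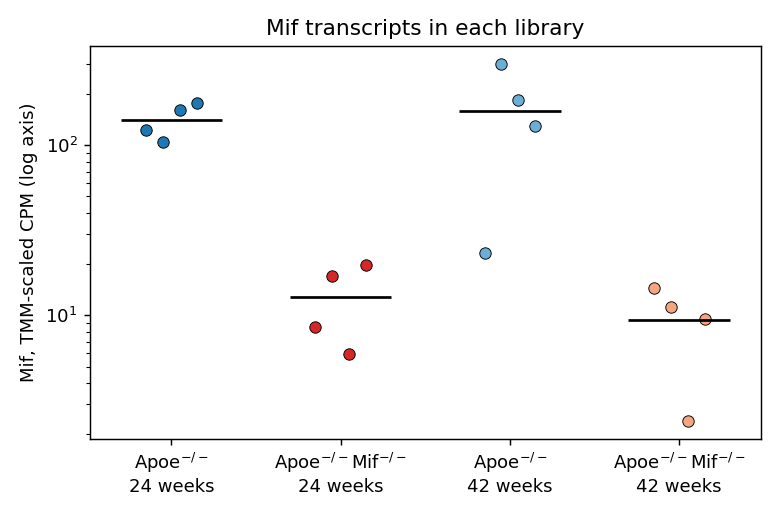
Mif transcripts in TMM-scaled CPM on a log axis for each of the 16 libraries by genotype and diet duration, with points for libraries and bars for group means. The 8 libraries of Apoe-/-Mif-/- mice lie at or below 19.9 CPM and the 8 of Apoe-/- mice at or above 23.2 CPM.

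At 24 weeks, arteries without Mif held fewer transcripts of fat and of 3 fast-fibre muscle genes. Thrsp, a regulator of lipid synthesis in fat, fell from 1270 ± 1828 to 5.79 ± 4.11 CPM (SD, n = 4; log2 fold change -7.76 ± 1.37 SE, edgeR adjusted p = 0.0191). Plin1, the coat protein of adipocyte lipid droplets, fell from 297 ± 328 to 0.433 ± 0.186 CPM (log2 -9.39, adjusted p = 0.0466). The muscle genes Atp2a1, the calcium pump of fast fibres, Tnnt3, a fast troponin, and Myh4, a fast myosin, had log2 fold changes of -9.90, -9.63 and -10.50 (edgeR adjusted p = 0.0466 each). Myh4 rested on 1 animal, with 3827, 4, 19 and 9 counts in the Apoe-/- libraries and 0, 0, 0 and 3 in the others. The striated muscle list did not pass (7 members higher and 8 lower, camera adjusted p = 0.613) in 1 direction, but passed the mixed test of fry, which lets members move both ways (adjusted p = 0.0333), with 3 members higher and 4 lower when adjusted over the list alone. These 5 genes, all lower, were the whole set called among 10634. Of them, 2 had over 50% of their counts in 1 library. For Tnnt3, 1 library held 60.2% of the CPM summed over all libraries.

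The white adipocyte list fell with all 18 tested members lower (median log2 fold change -4.17, camera adjusted p = 4.96e-17; adjusted p = 0.148 with an estimated correlation). In it 2 members passed over all genes and 12 when adjusted over the list alone. The white adipocyte scores of the groups overlapped, with library 2 of the Apoe-/- mice at 4.28 and the Apoe-/-Mif-/- mice at 2.87 to 5.38 (exact permutation p = 0.0857, 0.456 after adjustment). The brown adipocyte list fell likewise in 9 of 9 members (median -6.01, camera adjusted p = 5.02e-06; adjusted p = 0.21 with an estimated correlation). edgeR passed 0 of them over all genes and 7 adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, was present at 1162 ± 1621 and 4.99 ± 7.95 CPM (adjusted p = 0.081). Fatty acid oxidation genes (16 of 17 lower, median -2.43, camera adjusted p = 3.94e-05; adjusted p = 0.346 with an estimated correlation) and oxidative phosphorylation genes (23 of 23 lower, median -1.50, adjusted p = 7.35e-05; adjusted p = 0.482 with an estimated correlation) fell too. In both, 0 members passed over all genes or adjusted over the list alone. Without library 1 of the Apoe-/- mice the brown adipocyte, fatty acid oxidation and oxidative phosphorylation lists no longer passed (adjusted p = 0.0629, 0.184 and 0.505). Hadh, an enzyme of fatty acid oxidation, had a log2 fold change of -3.86 (adjusted p = 0.317), and Uqcrfs1, a subunit of respiratory complex III, -2.92 (adjusted p = 0.345). Cholesterol synthesis genes fell (12 of 14 lower, median -1.50, camera adjusted p = 0.0106; adjusted p = 0.188 with an estimated correlation), 1 of them adjusted over the list alone and 0 over all genes. This call ended without library 3 of the Apoe-/- or library 2 of the Apoe-/-Mif-/- mice (adjusted p up to 0.116).

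Immune and vascular lists moved in both directions in the same comparison. MHC class II presentation rose (8 of 9 members higher, median 1.40, camera adjusted p = 0.000306; adjusted p = 0.148 with an estimated correlation). H2-Eb1, a class II beta chain, was present at 218 ± 119 and 680 ± 285 CPM (log2 1.64, edgeR adjusted p = 0.65). Cd74, the invariant chain and a receptor for MIF, was present at 188 ± 62.2 and 549 ± 351 CPM (adjusted p = 0.718). Macrophage genes (14 of 16 higher, median 0.845, adjusted p = 0.000587; adjusted p = 0.355 with an estimated correlation) and chemokines (11 of 16 higher, median 1.21, adjusted p = 0.00121; adjusted p = 0.148 with an estimated correlation) rose in camera. The monocyte attractant Ccl2 was present at 15.6 ± 15.5 and 145 ± 40.8 CPM (adjusted p = 0.533), and the Fc receptor Fcgr1 at 13.3 ± 12.8 and 169 ± 129 CPM (adjusted p = 0.533). Inflammatory cytokines and adhesion (adjusted p = 0.00896; adjusted p = 0.188 with an estimated correlation) and erythroid genes (adjusted p = 0.0097; adjusted p = 0.365 with an estimated correlation) were higher as well. So were foam cell genes (adjusted p = 0.0112; adjusted p = 0.617 with an estimated correlation), contractile smooth muscle (adjusted p = 0.0112; adjusted p = 0.589 with an estimated correlation) and interferon response (adjusted p = 0.0187; adjusted p = 0.346 with an estimated correlation). T and NK cell genes fell (12 of 13 lower, median -3.57, adjusted p = 0.00544; adjusted p = 0.482 with an estimated correlation), of which 2 passed when adjusted over the list alone and 0 over all genes. That call ended without library 4 of the Apoe-/- or library 2 of the Apoe-/-Mif-/- mice, and without the former its direction turned (adjusted p = 0.608). That library had a T and NK cell score of 7.30, against at most 2.36 in the other Apoe-/- libraries at 24 weeks, and also held thymocyte transcripts such as Rag1 at 235 CPM. Cd8b1, a CD8 chain, was present at 322 ± 619 CPM in Apoe-/- arteries, and 1 library held 89.7% of its CPM summed over all libraries. In these lists with higher genes, 0 members passed over all genes or adjusted over the list alone. The smooth muscle call ended without any 1 of 4 libraries (1 and 4 of the Apoe-/-, 3 and 4 of the Apoe-/-Mif-/- mice), up to an adjusted p of 0.19. The erythroid call ended without any 1 of 5 (2 and 3, and 2, 3 and 4), up to 0.405. The foam cell call ended without library 4 of the Apoe-/- or library 2 of the Apoe-/-Mif-/- mice, up to 0.344, and the interferon call without library 2 or 3 of the Apoe-/- mice, up to 0.103.

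In all, 14 of 32 lists passed camera at 24 weeks, 8 higher and 6 lower, and 0 passed with an estimated correlation or with the directional test of fry. By exact permutation of list scores the lowest p among the 14 was 0.0571 (0.456 after adjustment). Every library of Apoe-/-Mif-/- mice at 24 weeks lay in another plate row than the rest, so plate row and group could not be told apart here. The 5 calls became 0 under size factors in place of TMM, with limma voom, with the white adipocyte score as a covariate, with counts under 1% of the row maximum set to 0. They also became 0 without library 1 of the Apoe-/- mice or any 1 of the 4 Apoe-/-Mif-/- libraries, while DESeq2 called 207 genes. The covariate is a score whose genes include Thrsp and Plin1, so losing their calls with it is partly built in.

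At 42 weeks 1 list passed camera with its preset correlation, that of lipid-laden macrophages. The foam cell and lysosomal lipid list fell in arteries without Mif (13 of 19 members lower, median log2 fold change -0.762, camera adjusted p = 0.0368; adjusted p = 0.978 with an estimated correlation). Plin2, the coat protein of lipid droplets in foam cells, was present at 1604 ± 646 CPM with Mif and 410 ± 227 CPM without it (SD, n = 4; log2 -1.97, edgeR adjusted p = 0.179). Fabp5, a fatty acid binding protein of macrophages, was present at 800 ± 232 and 190 ± 76.2 CPM (log2 -2.08, adjusted p = 0.18). It was 1 of 32 lists, with 0 members passing over all genes or adjusted over the list alone. By exact permutation of list scores its p was 0.0857, while chemokines (median -1.36) had 0.0286 and the circadian clock (median 1.40) 0.0571, each 0.914 after adjustment. The call ended with size factors (adjusted p = 0.138) and with the white adipocyte score as a covariate (0.0939), with the direction unchanged. It also ended without library 2 or 4 of the Apoe-/- mice (0.313 and 0.0893) or library 1 or 4 of the Apoe-/-Mif-/- mice (0.158 and 0.119).

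No single gene passed at 42 weeks: edgeR called 0 of 10634, with 1835 at an unadjusted p under 0.05 against 532 expected by chance. limma gave 0 with voom and 0 on the deposited values, while DESeq2 called 902. The smallest p belonged to Prg4, which encodes the lubricating proteoglycan lubricin, at 160 ± 37.0 CPM with Mif and 3021 ± 4006 CPM without it (log2 4.24 ± 0.94 SE, adjusted p = 0.176). Kdm6b, a histone demethylase, Clasp1, Kifc2 and Ppme1 followed with log2 values of 7.39, 6.46, 6.59 and 6.44 (adjusted p = 0.176 each). Single libraries held 86.3%, 76.4%, 71.7% and 73.1% of their CPM summed over all libraries. White and brown adipocyte lists had medians of 1.27 and 3.08 here and did not pass (camera adjusted p = 0.138 each), though 6 brown adipocyte genes passed as higher and 1 as lower when adjusted over the list alone.

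**Figure D2:**
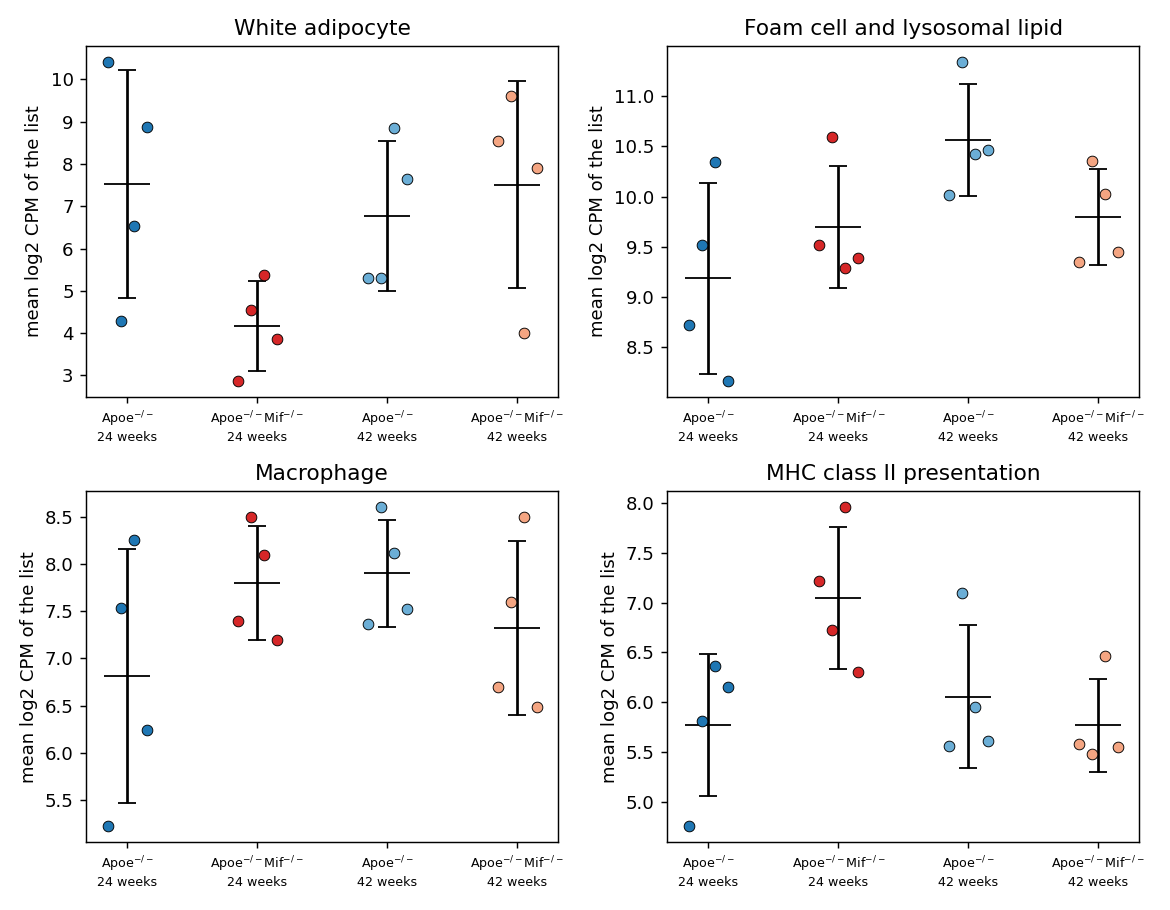
Scores of 4 gene lists, each the mean log2 CPM of its tested members, for every library by genotype and diet duration, with group mean ± SD (n = 4). The white adipocyte score averages 4.17 in Apoe-/-Mif-/- arteries at 24 weeks and 6.77 to 7.52 in the other groups, and the foam cell score is highest on average in Apoe-/- arteries at 42 weeks, at 10.6.

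Longer feeding of Apoe-/- mice went with more foam cell, macrophage and red cell transcripts. The foam cell list rose in 16 of 19 members (median log2 fold change 1.10, camera adjusted p = 5.63e-10; adjusted p = 0.454 with an estimated correlation). In it 6 members passed when adjusted over the list alone and 0 over all genes, and its exact permutation p was 0.0571 (0.548 after adjustment). Ctsd, the lysosomal protease cathepsin D, was present at 3237 ± 1796 CPM after 24 and 11390 ± 3394 CPM after 42 weeks (SD, n = 4; log2 1.82 ± 0.50 SE, edgeR adjusted p = 0.322). Lgals3, the macrophage lectin galectin-3, was present at 2115 ± 1890 and 7262 ± 2903 CPM (log2 1.78, adjusted p = 0.322). Macrophage genes rose in 13 of 16 members (median 1.23, camera adjusted p = 5.44e-06; adjusted p = 0.48 with an estimated correlation), 0 of them over all genes or the list alone. Tyrobp, an adaptor of myeloid receptors, was present at 176 ± 132 and 793 ± 670 CPM (adjusted p = 0.322) and Cd68 at 648 ± 682 and 2310 ± 1520 CPM (adjusted p = 0.326). Both lists passed in all 8 fits that left out 1 library, each at the preset correlation. Of 35 splits of these libraries, the real one included, 22 gave at least as many passing lists as the real 6.

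Erythroid genes rose as well (5 of 6 higher, median 3.70, camera adjusted p = 1.64e-05; adjusted p = 0.454 with an estimated correlation), 5 of them when adjusted over the list alone. The haemoglobin chain Hba-a1 was present at 167 ± 162 and 2249 ± 3320 CPM (adjusted p = 0.322). The erythroid list no longer passed without library 2 of the 42-week mice (adjusted p = 0.0576). Brown adipocyte genes fell in 9 of 9 members (median -4.63, camera adjusted p = 0.00385; adjusted p = 0.547 with an estimated correlation), 7 of them when adjusted over the list alone. Ucp1 was present at 1162 ± 1621 and 20.1 ± 8.09 CPM (adjusted p = 0.322) and Cox7a1 at 605 ± 988 and 24.4 ± 7.23 CPM (adjusted p = 0.322). Fatty acid oxidation (15 of 17 lower, median -1.91, camera adjusted p = 0.00317; adjusted p = 0.547 with an estimated correlation; 2 members adjusted over the list alone) and oxidative phosphorylation (22 of 23 lower, median -1.32, adjusted p = 0.00933; adjusted p = 0.73 with an estimated correlation; 0 members) fell. These 3 lists lost the call without library 1 of the 24-week mice, and each also without 1 library of the 42-week mice, in turn library 2, 4 and 1. Without library 1 of the 24-week mice the direction of the oxidative phosphorylation list turned as well. Their adjusted p then reached 0.55, 0.55 and 0.922.

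6 of 32 lists thus passed in a comparison that lay within 1 plate row, where each group filled its own stretch of the row. edgeR called 0 genes, with 1301 at an unadjusted p under 0.05, limma called 0 with voom and 0 on the deposited values, and DESeq2 called 372. The genes with the smallest p were Hba-a1, the predicted gene Gm3896 (log2 8.41), Shc3 (9.07), Coq8a (-4.98) and the unnamed gene 9930012K11Rik (8.35), each at an adjusted p of 0.322. Of the CPM summed over all libraries, single libraries held 97.9% for Gm3896, 90.6% for Shc3, 70.8% for Coq8a and 81.3% for 9930012K11Rik. In Apoe-/- mice Gm3896 had 6, 5, 4 and 1 counts at 24 weeks and 3, 6, 5 and 2156 at 42 weeks, and Shc3 had 1, 1, 0 and 1, then 1, 2, 14 and 749. In Apoe-/-Mif-/- mice Gm3896 had 0, 0, 0 and 4, then 12, 5, 3 and 5, and Shc3 had 0, 0, 0 and 2, then 51, 3, 65 and 0.

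In Apoe-/-Mif-/- mice, fat genes were higher after 42 than after 24 weeks. Thrsp rose from 5.79 ± 4.11 to 1668 ± 1634 CPM (SD, n = 4; log2 8.15 ± 1.39 SE, edgeR adjusted p = 0.0106), Car3, a carbonic anhydrase of adipocytes, from 5.38 ± 3.83 to 1127 ± 921 CPM (log2 7.71, adjusted p = 0.025) and Plin1 from 0.433 ± 0.186 to 213 ± 239 CPM (log2 8.91, adjusted p = 0.0401). The white adipocyte list rose in 17 of 18 members (median 4.29, camera adjusted p = 1.36e-16; adjusted p = 0.416 with an estimated correlation), of which 3 passed over all genes and 13 when adjusted over the list alone. Its exact permutation p was 0.0857 (0.548 after adjustment). Brown adipocyte genes rose in 8 of 9 members (median 3.83, adjusted p = 0.000987; adjusted p = 0.734 with an estimated correlation; 5 adjusted over the list alone against 0 over all genes) and oxidative phosphorylation in 22 of 23 (median 1.07, adjusted p = 0.00245; adjusted p = 0.92 with an estimated correlation; 0 over the list alone). Ucp1 was present at 4.99 ± 7.95 and 340 ± 626 CPM (adjusted p = 0.114). Without library 2 of the 42-week mice the brown adipocyte and oxidative phosphorylation calls ended (adjusted p = 0.309 and 0.324).

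Chemokines fell with time in these mice (13 of 16 lower, median -1.50, camera adjusted p = 0.00864; adjusted p = 0.477 with an estimated correlation), with Ccl5 at 32.8 ± 29.4 and 1.49 ± 1.15 CPM (edgeR adjusted p = 0.31). 0 chemokines passed over all genes or the list alone, and the list call ended without library 4 of the 42-week mice (adjusted p = 0.119). MHC class II presentation fell (7 of 9 lower, median -0.819, adjusted p = 0.0369; adjusted p = 0.734 with an estimated correlation). H2-Eb1 was present at 680 ± 285 and 52.9 ± 26.6 CPM (log2 -3.69, adjusted p = 0.0607), the 1 member that passed when adjusted over the list alone. The MHC class II call ended without any 1 of 5 libraries (1 and 3 at 24 weeks, 2, 3 and 4 at 42 weeks), up to an adjusted p of 0.149.

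13 genes rose and 0 fell, and 9 of the 13 had over 50% of their counts in 1 library. Apba2, which encodes a neuronal adaptor, was at 0 counts in all 4 libraries at 24 weeks and at 11, 3, 7 and 3533 counts at 42 weeks. It was at least 1740-fold higher against a floor of 3 counts over the group. That bound was set by library 4, which held 98.1% of the Apba2 CPM summed over all libraries. Without that library the Apba2 call ended (adjusted p = 0.182). Megf6 went from 0, 1, 0 and 0 to 8, 828, 33 and 4 counts (log2 11.42, adjusted p = 0.0401), Angel1 from 0, 0, 0 and 1 to 97, 799, 1 and 6 (log2 11.15) and Zan from 0, 4, 0 and 0 to 8, 1012, 207 and 2 (log2 10.29). Hic2, Aldh6a1, Clcn2, Armh3 and Il34, a ligand of the macrophage colony-stimulating factor receptor, rose by log2 values of 9.69, 9.63, 8.94, 8.46 and 8.89 (adjusted p = 0.0401, 0.0401, 0.0491, 0.0429 and 0.0429). This comparison also crossed the plate rows. The 13 calls became 0 with the white adipocyte covariate, with counts under 1% of the row maximum set to 0, or without any 1 of the 4 libraries at 24 weeks. Size factors gave 22 calls, DESeq2 562, voom 5 and the deposited values 2. The covariate is built from genes that include Thrsp, Car3 and Plin1, so losing their calls with it is partly built in.

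**Figure D3:**
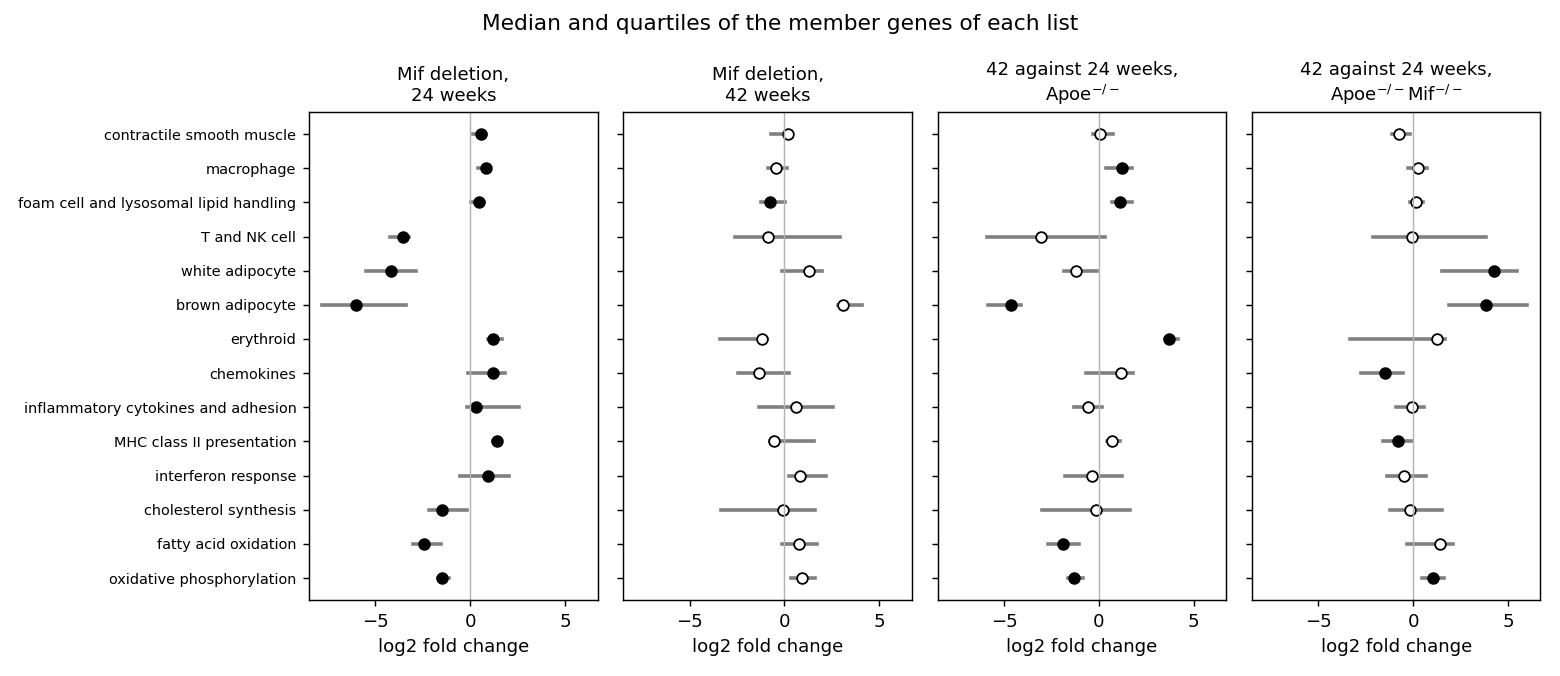
Median (point) and quartiles (line) of the fitted log2 fold changes of the members of the 14 lists that passed camera in at least 1 comparison, for Mif deletion at 24 and 42 weeks and for 42 against 24 weeks in each genotype; filled points passed. The white adipocyte median is -4.17 for Mif deletion at 24 weeks and 4.29 for diet duration in Apoe-/-Mif-/- mice, a pair of comparisons that share 4 libraries.

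Averaged over both durations, the white adipocyte list was lower without Mif, which came from the 24-week mice, in a comparison that crosses plate rows. At 42 weeks its median was 1.27, and Thrsp was present at 545 ± 451 CPM with Mif and 1668 ± 1634 CPM without it (SD, n = 4). White adipocyte genes fell in 17 of 18 members (median -1.63, camera adjusted p = 2.36e-06; adjusted p = 0.787 with an estimated correlation; 6 adjusted over the list alone against 0 over all genes), with Thrsp at a log2 fold change of -3.07 and Car3 at -3.36 (edgeR adjusted p = 0.125 each). T and NK cell genes fell in 12 of 13 (median -2.19, adjusted p = 0.0451; adjusted p = 0.912 with an estimated correlation; 1 over the list alone), with Trac, the T cell receptor alpha constant region, at -5.24 (adjusted p = 0.126). Interferon-response genes rose in 8 of 11 (median 0.261, adjusted p = 0.0451; adjusted p = 0.787 with an estimated correlation; 1 over the list alone), with Usp18 at 4.82 (adjusted p = 0.137). Mif itself had a log2 fold change of -3.78 ± 0.85 SE (adjusted p = 0.109).

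edgeR called 0 genes in the average, with 1380 at an unadjusted p under 0.05, limma called 0 with voom and 0 on the deposited values, and DESeq2 called 392. Among the smallest p were those of the transcription factor Deaf1 (log2 5.21), Trpm3 (-7.38), Adamts16 (-6.47) and Gm5421 (-6.39), each at an adjusted p of 0.109. Trpm3 and Gm5421 were at 0 counts in the row C libraries, so their fitted values are no bound on a fold. Of the CPM summed over all libraries, single libraries held 54% for Deaf1, 90.7% for Adamts16 and 94.3% for Gm5421. In Apoe-/- mice at 24 and then 42 weeks, Trpm3 had 100, 44, 9 and 61, then 47, 119, 13 and 0 counts. Adamts16 had 38, 4, 8 and 192, then 1, 5, 12 and 1518, and Gm5421 had 7, 86, 24 and 6, then 371, 7, 5 and 7. In Apoe-/-Mif-/- mice at 42 weeks Trpm3 had 3, 0, 1 and 1, Adamts16 4, 4, 48 and 4, and Gm5421 10, 4, 12 and 7, and Adamts16 had 0, 0, 0 and 1 at 24 weeks. The T and NK cell call ended without any 1 of 7 libraries, among them library 4 of the Apoe-/- mice at 24 weeks, without which its direction turned (adjusted p = 0.997). The interferon call ended without any 1 of 8 libraries, up to 0.165.

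The difference between genotypes changed with duration for fat genes, in a comparison that crosses plate rows. For Thrsp the genotype difference at 42 weeks exceeded that at 24 weeks by 9.37 ± 1.68 (SE) on the log2 scale (edgeR adjusted p = 0.0136). The excess was 12.58 for Plin1 (adjusted p = 0.0136), 9.27 for Dgat2, which makes triglycerides (adjusted p = 0.0176), and 11.89 for Ucp1 (adjusted p = 0.0136). White adipocyte genes had positive interaction terms in 17 of 18 members (median 5.36, camera adjusted p = 1.61e-12; adjusted p = 0.33 with an estimated correlation), with 5 passing over all genes and 11 adjusted over the list alone. Brown adipocyte genes had them in 9 of 9 (median 7.93, adjusted p = 7.66e-06; adjusted p = 0.33 with an estimated correlation), with 5 and 7. Elovl3 and Otop1 in that list were at 0 counts in a group, and with both at their bound the median was 7.93 as well.

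H2-Eb1 changed in the opposite sense, with 218 ± 119 and 680 ± 285 CPM at 24 weeks and 477 ± 132 and 52.9 ± 26.6 CPM at 42 weeks without and with Mif deletion (SD, n = 4; interaction log2 -4.82 ± 1.11 SE, adjusted p = 0.0388). Its CPM were spread, with 16.3% of their sum over all libraries in the library that held most. The MHC class II list had a negative median (-1.18, camera adjusted p = 0.00409; adjusted p = 0.33 with an estimated correlation; 1 member passing over all genes and 1 adjusted over the list alone), and the call ended without library 2 of the Apoe-/- mice at 42 weeks (adjusted p = 0.0645). Foam cell genes had a negative median (15 of 19 negative, median -1.22, adjusted p = 0.000365; adjusted p = 0.581 with an estimated correlation; 3 adjusted over the list alone against 0 over all genes). They passed in all 16 fits without 1 library, each at the preset correlation. Fabp5 was at -3.73 (adjusted p = 0.077) and Lgals3 at -2.29 (adjusted p = 0.149). Macrophage genes were negative (13 of 16 negative, median -1.39, adjusted p = 0.000942; adjusted p = 0.581 with an estimated correlation; 0 over the list alone), with C1qa at -1.73 (adjusted p = 0.336). Chemokines (median -1.91, adjusted p = 0.000365; adjusted p = 0.285 with an estimated correlation; 0 over the list alone) and erythroid genes (median -2.49, adjusted p = 0.00409; adjusted p = 0.581 with an estimated correlation; 1 over the list alone) were negative too, the latter not without any 1 of 6 libraries, where the adjusted p reached 0.452. Fatty acid oxidation (median 3.23, adjusted p = 0.000365; adjusted p = 0.581 with an estimated correlation; 7 over the list alone) and oxidative phosphorylation (median 2.19, adjusted p = 4.76e-05; adjusted p = 0.581 with an estimated correlation; 5 over the list alone) were positive. Their calls ended without library 1 of the Apoe-/- mice at 24 weeks (adjusted p = 0.115 and 0.0528). These lists had 0 members passing over all genes, with Hadha at 4.48 (adjusted p = 0.092). In the mixed test of fry, chemokine, MHC class II, cholesterol synthesis and senescence genes passed in the interaction (adjusted p = 0.0254 each), as did matrix-degrading proteases and the circadian clock (adjusted p = 0.0468 each).

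73 genes passed, 62 with a positive and 11 with a negative term, and 38 of them had over 50% of their counts in 1 library. Muscle genes were among them, with Tnnt3 at 11.29, Myh4 at 10.61 and Acta1, skeletal actin, at 8.99 (adjusted p = 0.0237, 0.0403 and 0.0432). So were Trbc1, a T cell receptor chain, at 12.72, Kdr, the endothelial receptor of vascular growth factor, at 9.64, Cidea at 8.85, Cox8b at 7.93 and Pck1 at 8.67. Negative terms with counts in at least 2 libraries of each group included Col4a4 (-12.30), Rgs4 (-11.44), Orc5 (-10.71), Mcat (-9.14), Mrgpre (-8.60), Unc119 (-8.09) and Daglb (-7.04), and positive ones Ago4 (12.97) and Tmem45b (12.95). The largest fitted terms belonged to genes with few libraries behind them. Their counts per library follow for Apoe-/- and then Apoe-/-Mif-/- mice at 24 weeks, and the same at 42 weeks. Poln had 261, 13, 6 and 176, then 0 in all 4, then 0, 1, 1 and 1, then 0, 0, 34 and 81. Mmp28, a matrix metalloproteinase, had 67, 2, 2 and 296, then 0 in all 4, then 2, 1, 2 and 2, then 3, 0, 342 and 332. Bcl11b, a T cell transcription factor, had 14, 47, 2 and 561, then 0, 0, 0 and 1, then 0, 0, 3 and 2, then 1, 145, 52 and 0. Hlf had 22, 0, 2 and 147, then 0, 1, 0 and 0, then 0, 3, 0 and 3, then 3, 426, 0 and 279. Adtrp had 115, 1, 1 and 40, then 0 in all 4, then 1, 0, 21 and 2, then 538, 2, 1 and 44. Elovl3, a fatty acid elongase of brown fat, had 392, 0, 6 and 379, then 0 in all 4, then 0, 2, 3 and 2, then 4, 6, 1 and 27. Unc5d had 176, 0, 1 and 84, then 0 in all 4, then 0, 36, 3 and 1, then 341, 3, 139 and 1. Klhdc7a had 1051, 1, 32 and 39, then 0 in all 4, then 1, 2, 2 and 6, then 8, 0, 74 and 4. F10, coagulation factor X, had 0, 1, 0 and 0, then 72, 0, 31 and 2, then 8, 98, 6 and 0, then 1, 0, 0 and 1.

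The 73 calls became 0 with limma voom, with the deposited values, with the white adipocyte covariate, without the shallowest and the least correlated library, and with counts under 1% of the row maximum set to 0, while DESeq2 called 546. They also ended without library 1 of the Apoe-/- or library 1 of the Apoe-/-Mif-/- mice at 24 weeks, or without library 1, 2 or 4 of the Apoe-/- mice at 42 weeks. Plate row could not be told apart from the Apoe-/-Mif-/- group at 24 weeks, which is part of the term. For H2-Eb1 that group had the highest mean (680 CPM), and the row B group of Apoe-/-Mif-/- mice at 42 weeks had the lowest (52.9 CPM). This gene therefore does not set the term apart from plate row. The covariate is built from genes that include Thrsp, Plin1, Dgat2 and Pck1, so losing their calls with it is partly built in.

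Transcripts held by 1 library turned up in the other libraries mostly within the same plate row. Of 87 genes with at least 500 counts in 1 row B library that held over 95% of their counts, a median of 73.6% (36.8% to 95.8%) were detected in each other row B library and 12.6% (6.90% to 19.5%) in each row C library. Of 15 such genes of row C, 90% were detected in the median row C library and 13.3% in the median row B library. The counts found amounted to 0.198% of those in the holding library within row B and 0.0332% from row B to row C.

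**Figure D4:**
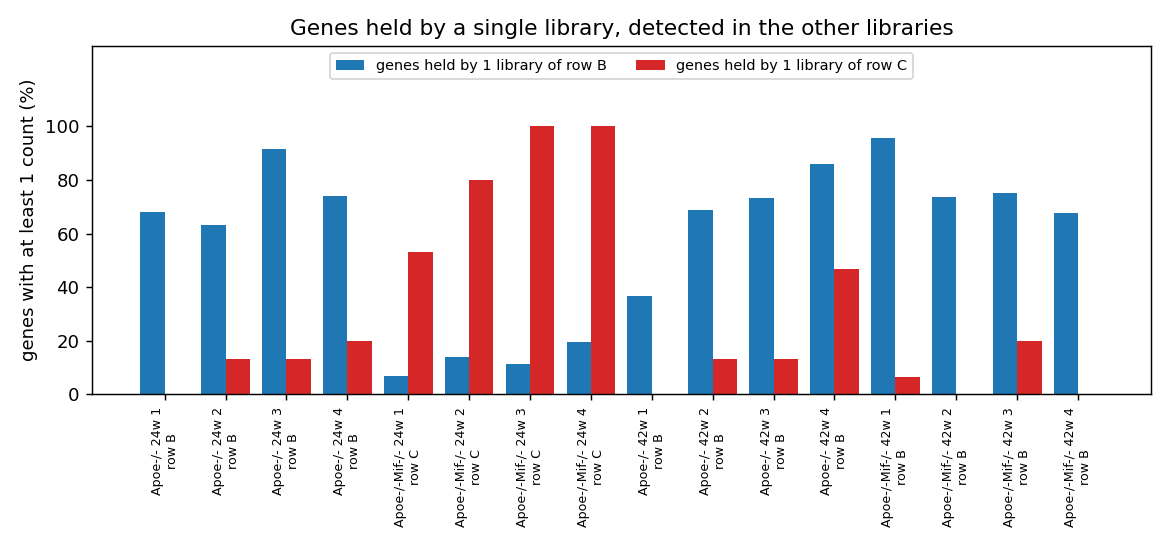
Share of the genes held almost wholly by 1 library of row B (87 genes, blue) or row C (15 genes, red) that had at least 1 count in each other library, in percent. Row B libraries detect 36.8% to 95.8% of the row B genes and row C libraries 6.90% to 19.5%.

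Across all comparisons 14 of the 32 lists passed camera at least once and 18 never did. The lowest camera adjusted p of the latter was 0.114 for plasma cell genes (duration in Apoe-/-Mif-/- mice), 0.125 for receptors and relatives of MIF, 0.13 for osteochondrogenic genes, 0.138 for cholesterol efflux, 0.144 for senescence, 0.147 for fibroblast and collagen matrix and 0.184 for striated muscle and for the circadian clock. It was 0.272 for B cell genes, Wnt signalling, immediate early genes and neighbours of Mif on its chromosome, 0.286 for matrix-degrading proteases, 0.374 for proliferation, 0.539 for endothelial genes, glycolysis and the unfolded protein response, and 0.697 for complement. Ddt, the paralog and neighbour of Mif, was present at 47.6 ± 86.5 and 7.42 ± 8.22 CPM at 24 weeks and 3.54 ± 5.15 and 33.5 ± 26.7 CPM at 42 weeks with and without Mif (SD, n = 4; exact permutation p = 0.6 and 0.0857). Library 1 of the Apoe-/- mice at 24 weeks held 177 CPM of Ddt against at most 6.64 CPM in the other 3, so the direction at 24 weeks rested on that mouse. Across 10634 genes, which are not independent replicates, the genotype effects at 24 and 42 weeks had a Pearson correlation of -0.0326, and the duration effects in the 2 genotypes -0.0153.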

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

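All tests of explanations in this part were chosen or written down after the results they bear on had been seen, and the comparisons themselves were planned. 5 of 84 groups of 4 libraries held a library far from the other 3, where chance would give 4.2. These were the mitochondrial share of library 4 of the Apoe-/-Mif-/- mice at 24 weeks (3.065%), its interferon-response score (3.58), the Apoe level of library 4 of the Apoe-/- mice at 42 weeks (1127 CPM) and of library 3 of the Apoe-/-Mif-/- mice at 42 weeks (194.2 CPM), and the MHC class II score of that last library (6.47). GFP, a reporter outside the tests, had 46 counts over 12 libraries, with at most 10 in 1 library and over 3 in 6, and TDTOM had 0.

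The genotype difference changed with duration for 73 genes (edgeR) and 9 lists (camera at the preset correlation), in a comparison that crosses plate rows. The list medians of the interaction were -1.39 for macrophage, -1.22 for foam cell, 5.36 for white adipocyte, 7.93 for brown adipocyte, -2.49 for erythroid, -1.91 for chemokine, -1.18 for MHC class II, 3.23 for fatty acid oxidation and 2.19 for oxidative phosphorylation genes. The fitted terms of named genes, which depend on the prior count where a group is at 0 as it was for 6 of the 31, were 15.11 for Poln, 15.08 for Mmp28, 14.93 for Bcl11b, 14.85 for Hlf, 13.86 for Adtrp, 13.81 for Elovl3, 13.57 for Unc5d and 13.57 for Klhdc7a. They were 12.97 for Ago4, 12.95 for Tmem45b, 12.72 for Trbc1, 12.58 for Plin1, 11.89 for Ucp1, 11.29 for Tnnt3, 10.61 for Myh4, 9.64 for Kdr, 9.37 for Thrsp, 9.27 for Dgat2, 8.99 for Acta1, 8.85 for Cidea, 8.67 for Pck1 and 7.93 for Cox8b. The negative terms were -12.65 for F10, -12.30 for Col4a4, -11.44 for Rgs4, -10.71 for Orc5, -9.14 for Mcat, -8.60 for Mrgpre, -8.09 for Unc119, -7.04 for Daglb and -4.82 for H2-Eb1.

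Other groupings of the same libraries were compared with the real one, which is included in the numbers given. They gave as many changed genes in 3 of 35 splits for Mif deletion at 24 weeks (5 genes, highest other 13), 35 of 35 at 42 weeks (0, highest other 1). The number was 35 of 35 for duration in Apoe-/- mice (0, highest other 0), 1 of 35 for duration in Apoe-/-Mif-/- mice (13, highest other 10), 100 of 100 drawn for the average (0, highest other 36) and 1 of 100 drawn for the interaction (73, highest other 72). For lists the numbers were 4 of 35 (14, highest other 19), 31 of 35 (1, highest other 8), 22 of 35 (6, highest other 14), 9 of 35 (5, highest other 7), 80 of 100 (3, highest other 13) and 25 of 100 (9, highest other 12). Other groupings seldom did as much (a share under 0.05) for the gene counts of duration in Apoe-/-Mif-/- mice and of the interaction, and not for the other counts. The real splits of both comparisons that involve only row C and part of row B, Mif deletion at 24 weeks and duration in Apoe-/-Mif-/- mice, were also splits by plate row. The real split behind the average and the interaction likewise divided the 24-week libraries by plate row. Row could therefore not be told apart from the grouping in either gene count with a share under 0.05.

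The low level of white adipocyte transcripts in Apoe-/-Mif-/- arteries at 24 weeks had a median log2 fold change of -4.17. Reads passing between libraries of a plate row would lift such transcripts in row B. The median was -3.91 with counts under 1% of the row maximum set to 0, so the fall did not rest on counts under that share. That setting leaves the highest counts, which set the group means, as they were, so it does not decide on carry-over. With all libraries thinned to the shallowest the median was -4.20. Thinning keeps each gene's expected share of its library, so this value cannot decide on depth. Different amounts of surrounding fat in the sections may account for the low level. In the brown adipocyte list, which shares no member with the white list, 9 of 9 genes were lower as well. That call ended without library 1 of the Apoe-/- mice (camera adjusted p = 0.0629). A lower brown list does not tell section content apart from a genotype effect on fat or from plate row. A genotype effect on fat around the vessel stays open and untested, as does plate row, which could not be told apart from the group.

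The foam cell list was higher after 42 than after 24 weeks in Apoe-/- mice within 1 plate row, by a median of 1.10. Thinning to equal total counts left a median of 1.04. As thinning keeps each gene's expected share of its library, this value cannot decide on depth. A lower share of surrounding tissue in the 42-week sections stays open. The fibroblast score, part of which comes from that tissue, differed by -0.157 (exact permutation p = 0.8), which decides neither way. The white adipocyte score differed by -0.751 and the striated muscle score by -1.11 (exact permutation p = 0.6 and 0.4), which do not decide either. In the brown adipocyte list 9 of 9 genes were lower (median -4.63), which goes with a lower share. That list call ended without library 1 of the 24-week mice or library 2 of the 42-week mice (camera adjusted p up to 0.55). More lipid-laden macrophages after longer feeding, age and section plane stay open as well.

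Mif counts in mice without Mif exceeded an estimate of carry-over at 24 weeks and not clearly at 42 weeks. From the rate at which genes of a single library turned up elsewhere, 8.37 Mif counts were expected in the 4 libraries at 24 weeks against 168 observed (ratio 20.1, 95% interval 12.6 to 40), and 44.3 against 68 at 42 weeks (ratio 1.53, 1.16 to 1.98). The rate depends on which genes count as held by 1 library, and 4 settings were examined after seeing the data. The other 3 gave ratios of 5.30, 5.69 and 5.83 at 24 weeks, with lower bounds of at least 3.46. At 42 weeks they gave 0.878, 1.02 and 1.06, with intervals that hold 1. The observed counts therefore exceeded the estimate at 24 weeks under all 4 settings, and at 42 weeks the answer changed with the setting. The required share in 1 library leaves out genes with more carry-over, so the estimate may be too low. With that share lowered from 95% to 90%, the expected counts at 24 weeks went from 8.37 to 31.7. These values thus cannot exclude carry-over at 24 weeks. Pseudogene reads may contribute at 24 weeks, where they came to 0.345 of the Mif counts, a ratio that decides neither way, and transcription from a deleted allele was not tested.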

How the results depend on the processing

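Leaving out a doubted pair (the shallowest and the least correlated library), thinning, and the plate-row setting (counts under 1% of the row maximum set to 0) were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the labels give each library its own mouse and no number shared between groups. The cause of the changes below was not tested, except that stricter filters and thinning leave fewer genes or counts. For changed genes at 24 weeks (5) the counts were 0 with size factors, with the covariate, with 2 groups alone, with voom, with the deposited values and with the plate-row setting, 1 with the stricter filter, thinned, or without the doubted pair, 8 at an adjusted p under 0.1, 117 unfiltered and 207 with DESeq2. At 42 weeks (0) they were 25 with 2 groups alone, 150 unfiltered and 902 with DESeq2. For duration in Apoe-/- mice (0) they were 18 unfiltered and 372 with DESeq2, and for the average (0) 141 and 392. For duration in Apoe-/-Mif-/- mice (13) they were 0 with the covariate and the plate-row setting, 1 thinned, 2 with the deposited values, 3 with the stricter filter, 5 with voom, 22 with size factors, 26 under 0.1, 419 unfiltered and 562 with DESeq2. For the interaction (73) they were 0 with the covariate, voom, the deposited values, the plate-row setting and without the doubted pair, 5 thinned, 21 with the stricter filter, 188 under 0.1, 426 unfiltered and 546 with DESeq2. Under the plate-row setting the called genes kept their sign in 4 of 4, 12 of 12 and 69 of 69 still tested, and their median absolute log2 values were 9.63 and 9.21, 9.63 and 8.59, and 10.9 and 12.4 before and after. Their median SE widened from 1.98 to 2.84, from 1.98 to 2.70 and from 2.47 to 3.61. For lists the counts with an estimated correlation or the directional fry test were 0 in each comparison, and with the covariate 5, 0, 3, 2, 2 and 4 in place of 14, 1, 6, 5, 3 and 9, of which 4, 0, 3, 0, 1 and 3 were the same lists. At 42 weeks 0 passed with size factors and 2 thinned or with the plate-row setting, and in the average 1 without the doubted pair and 6 thinned. Without 1 library the gene counts ran from 0 to 21, 0 to 1, 0 to 0, 0 to 33, 0 to 1 and 0 to 124 in the order of the report, and the list counts from 11 to 17, 0 to 6, 4 to 9, 2 to 6, 1 to 7 and 8 to 12. Gene counts at 24 weeks were 21, 17 and 2 without library 2, 3 or 4 of the Apoe-/- mice. For duration in Apoe-/-Mif-/- mice they were 22, 2, 33 and 21 without library 1, 2, 3 or 4 at 42 weeks. 

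Lmod1 at 24 weeks turned to a log2 fold change of -0.005 with voom. Directions also turned for Eci1 at 24 weeks (0.662 with the covariate), and Pck1 (-1.35) and Cox8b (-0.934) in the interaction with the covariate. They turned for Mif over time in Apoe-/- mice (-0.146 with voom, -0.11 with the plate-row setting) and in Apoe-/-Mif-/- mice (0.11 with size factors, 0.088 with DESeq2, 0.01 with the deposited values). The oxidative phosphorylation list turned with the covariate at 24 weeks (adjusted p = 0.186), over time in Apoe-/-Mif-/- mice (0.265) and in the interaction (0.724). Without 1 library, Apoe ran from -1.60 to 0.035 and Alas2 from -1.213 to 6.56 at 24 weeks. Mif over time ran from -0.262 to 0.614 in Apoe-/- and from -0.731 to 0.005 in Apoe-/-Mif-/- mice, where Apoe ran from -1.737 to 1.74, and the Apoe interaction ran from -4.366 to 0.327. All-gene median log2 values with TMM and with size factors were -0.181 and -0.122, 0.0928 and 0.28, -0.124 and 0.155, 0.124 and 0.54, and 0.264 and 0.373 for the interaction. DESeq2 gave no adjusted p for 1166 to 1564 genes.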

Other observations

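The values in this part were looked at after the data were seen, and no explanation was tested for them. Library 4 of the Apoe-/- mice at 24 weeks held transcripts of developing T cells. Rag1, which cuts antigen receptor genes for rearrangement, was present there at 235 CPM, Dntt, the template-free polymerase of receptor junctions, at 182 CPM, Ptcra, the pre-T cell receptor alpha chain, at 160 CPM and Arpp21 at 370 CPM. Of 3 thymic epithelial genes looked up, single ones appeared elsewhere in the same group. Foxn1 was at 73.1 CPM in library 3 and Aire, which drives tissue antigens in the thymus, at 91.4 CPM in library 1. Library 3 had 6 counts of Aire and 2 of Rag1, and library 1 had 2 counts of Foxn1 and 1 of Rag1. Psmb11 had 0 counts in every library of this group. The thymocyte list had 4 tested genes, as had the germinal centre, neutrophil and neighbouring epithelium lists, and the nerve list had 3, so none of these 5 was tested as a list.

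Red cell transcripts were most abundant in library 2 of the Apoe-/- mice at 42 weeks, where the erythroid score was 10.3, against a group mean of 7.07 ± 2.34 (SD, n = 4). Fat and muscle transcripts in Apoe-/- arteries at 24 weeks were spread unevenly over mice, with white adipocyte scores between 4.28 and 10.4 and striated muscle scores between 2.25 and 6.76. In Apoe-/-Mif-/- arteries at the same time the ranges were narrower, 2.87 to 5.38 and 3.45 to 5.06.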
